A study of Rattus norvegicus with 2 samples.

How the data were processed

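Single-cell RNA sequencing was done on 2 cultures of rat (Rattus norvegicus) cortical neural stem cells, which per the labels came from embryonic day 14.5 Sprague-Dawley cortex. The cultures were kept with FGF2, a growth factor that holds such cells undifferentiated. Per the labels' protocols, 1 culture received 30 µM ZD7288, a blocker of hyperpolarisation-activated cyclic nucleotide-gated (HCN) channels, in 0.2% DMSO, and the other received DMSO alone. Exposure lasted 48 h, with medium and compound renewed at 24 h. The label of the treated culture spells the compound ZD2788, and the series title and the treatment protocol spell it ZD7288, which is used here. Per the labels' protocols, cells were captured with the 10x Chromium 3′ kit, version 2, which tags each captured molecule with a unique molecular identifier (UMI) so that amplification copies are counted once.

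The deposited matrix held raw UMI counts of 25399 genes in 4691 cell barcodes of both libraries together, with no normalisation. Per the submitters' processing notes the counts were made with Cell Ranger, and the matrix header gives software version 3.0.2. The genome build, the gene annotation, the rule by which barcodes were kept and any equalisation of depth between the libraries are not given in the sources used here, so no coordinates are printed. The number after the hyphen of each barcode gave its library, matched to the number at the start of each sample title. No other source used here gives this match, and the direction of every ratio rests on it. Gene symbols were those of the deposited gene table, with list members matched by symbol or by synonyms from a reference table of assembly GRCr8 that served for names only. Of 941 symbols written in 35 gene lists, 895 were matched.

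Cells were kept with at least 1000 UMIs, at least 500 detected genes and at most 10% mitochondrially encoded UMIs. This left 732 of 842 vehicle barcodes and 3135 of 3849 ZD7288 barcodes. UMI counts were summed over the kept cells of each library and scaled to a library total of 1000000 (counts per 1000000 UMIs, CPM). A gene was called measured with at least 20 CPM in the higher library. The ratio of ZD7288 to vehicle CPM was given with an exact 95% interval (Clopper-Pearson, on the treated share of both summed counts), CPM values with exact Poisson intervals and shares of cells with exact binomial intervals. These intervals cover counting error only. With 1 library per group there was no test, no p-value and no standard error, and cells were not treated as replicates. A count of 0 allowed up to 3 counts, which was 0.192 CPM in the vehicle library and 0.0407 CPM in the ZD7288 library.

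Before the data were examined, the design, the gene lists, the cell type markers, the size rules and a set of other settings were fixed. Genes were called higher or lower at a ratio of at least 1.5-fold, and members of a list at a log2 ratio of at least 0.32 in either direction. Named genes were the 12 measured genes with the largest and the 12 with the smallest ratio among those with a gene symbol, the HCN channel genes, and in each list up to 4 measured members with the largest differences past the list rule, or the 2 with the highest CPM where none passed. Identifiers without a gene symbol were left out. Values of some genes under this rule are not reported here. Within groups of cells the 6 largest and 6 smallest ratios were taken, and in clusters the 5 leading genes. Other genes that are named were chosen after their values were seen, and the text says so. The median log2 ratio of each list with at least 3 measured members was set beside 10000 random lists of the same size matched on mean CPM, as a description of these libraries only.

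For shares of cells, every cell was thinned to 2000 UMIs, which left out 8 vehicle and 179 ZD7288 cells that were shallower. The threshold set beforehand was 3 UMIs over the S phase and G2/M lists. Clusters came from log-normalised counts of 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 0.5, with no batch correction. Members of the S phase and G2/M lists, ribosomal protein genes and mitochondrially encoded genes were left out of the variable genes. Doublets were scored against simulated doublets and marked at 0.8% of a library per 1000 cells, which gave 83 cells that stayed in the analysis and were left out in another setting. Other settings covered the scaling of the libraries, the cell filter, the weight and depth of cells, doublets, the CPM floor, the size rule, the thinned depth, the threshold and the clustering. The comparison of treated cells with each other, counts of ATF4 list UMIs per group of cells, collagen counts per cluster, thresholds of 10 and 15 UMIs, ranges below and from 10 UMIs, the removal of a low-UMI cluster, the lowest 25% of treated cells by UMIs and by mitochondrial share and the comparison of single treated clusters with the vehicle library were added after the data were seen.

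The ratio step was tested on simulated counts drawn from the profile of the vehicle library with counting error only. The 4472 genes with at least 20 CPM in that library were scored, 200 of them with altered levels. The 95% interval held the true ratio for 94.9% of genes, 100% of the genes altered 2-fold passed the 1.5-fold rule in the right direction, and 0% of the unaltered genes passed it. The simulation held no differences between cultures and no genes with few vehicle UMIs. Its 0% is therefore not an error rate of the rule in the real comparison. Of the simulated cells, 99.7% fell in a cluster led by their own population. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.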

Results

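Neural stem cells from rat cortex were profiled by droplet single-cell RNA sequencing after 48 h with ZD7288 or with vehicle. The comparison addresses how their transcriptome differs after exposure to this HCN channel blocker. Each group was 1 culture and 1 library, so culture, library and treatment are the same split and every difference compares 2 libraries without a replicate check. The vehicle library held 732 cells after filtering, with 15611454 UMIs and a median of 17119 UMIs and 3392 genes per cell. The ZD7288 library held 3135 cells, with 73681950 UMIs and a median of 23001 UMIs and 4024 genes per cell. The median share of mitochondrially encoded UMIs was 5.84% in vehicle cells and 4.70% in treated cells. Barcodes above the mitochondrial limit made up 12.4% (95% interval 10.2 to 14.8) of vehicle barcodes and 14.2% (13.1 to 15.3) of treated barcodes. Kept cells with fewer than 5000 UMIs were more frequent in the treated library, at 9.47% (8.47 to 10.6) against 3.01% (1.89 to 4.52).

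Transcripts of Hcn2, Hcn3 and Hcn4, which encode channels of the family that ZD7288 blocks, were few in these cells, and none of these genes reached the level called measured. Hcn3 (ENSRNOG00000020444) had 27 UMIs in the vehicle library and 66 in the treated library, or 1.73 CPM (1.14 to 2.52) and 0.896 CPM (0.693 to 1.14). Hcn2 had 0 and 2 UMIs, and Hcn4 had 0 and 6, where the count of 0 in the vehicle library allows up to 0.192 CPM. These counts hold no measure of channel block, so effects through HCN channels and through other targets of the compound cannot be told apart. Of the voltage-gated potassium channel list 1 gene was measured, Kcna2, which was 1.75-fold lower (1.64 to 1.87) in the treated library. The lists of other potassium channels and of sodium and calcium channels had 0 measured members.

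Genes of the ATF4 and amino acid response, which cells use to make and import amino acids under stress, were higher in the treated library, with the largest median of the fixed lists. Of 29 measured members, 28 were higher and 0 lower by the list rule, with a median log2 ratio of 1.82 that lay above all of 10000 random lists (central range -0.07 to 0.25). Trib3, a pseudokinase induced by ATF4, stood at 66.0 CPM against 0.705 CPM, a ratio of 93.6 (52.3 to 188). The cystine transporter gene Slc7a11 was 18.5-fold higher (14.1 to 24.9), the mitochondrial phosphoenolpyruvate carboxykinase gene Pck2 15.5-fold (12.4 to 19.6) and the glutathione-degrading enzyme gene Chac1 14.8-fold (11.5 to 19.6). Asparagine synthetase, Asns, rested on deeper counts and was 9.04-fold higher (8.31 to 9.86), at 320.3 CPM against 35.4 CPM. Summed over the list, the level was 7134 CPM in the treated and 2158 CPM in the vehicle library. Slc38a2 was the member that did not pass the list rule, at a ratio of 0.844 (0.788 to 0.906), and it is named here after its value was seen, as are Atf4 itself, at 2.25-fold (2.15 to 2.35), and Ddit3, at 3.13-fold (2.76 to 3.57).

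Across the transcriptome, 485 of 4823 measured genes were at least 1.5-fold higher and 251 at least 1.5-fold lower in the treated library. At 2-fold the counts were 139 and 61. Scaled by the median gene ratio in place of total UMIs, the counts at 1.5-fold were 388 higher and 319 lower. The largest ratio was that of Ifi27l2b, at 106-fold (59.0 to 212) over 11 vehicle UMIs. It belongs to a family of similar genes among which reads can be divided, so its level is uncertain. Ratios over few vehicle UMIs varied between settings, in both directions. The log2 ratio of Slc7a11 was 4.21 and, with each cell thinned to 2000 UMIs, 3.01. Those of Slc7a3 and Trib3 were 5.51 and 6.55 and, in cells below 10 cell cycle UMIs, 3.70 and 4.57. Those of Chac1, Pck2 and Nqo1 were 3.89, 3.95 and 3.45 and, in the same cells, 5.45, 5.29 and 4.79. There Trib3, Chac1, Pck2 and Nqo1 rested on 3, 1, 2 and 2 vehicle UMIs, with ratios of 23.7 (8.10 to 115), 43.6 (7.80 to 1723), 39.0 (10.8 to 322) and 27.7 (7.64 to 229). Each of these intervals holds the ratio of the same gene over whole libraries, so the shifts of these genes lie within counting error. Further genes among the 12 largest ratios were the cationic amino acid transporter gene Slc7a3 at 45.7-fold (35.6 to 59.7), the cysteine-forming enzyme gene Cth at 28.4-fold (21.8 to 37.8), the transcription factor gene Creb3l1 at 14.4-fold (9.64 to 22.5) and the inflammatory caspase gene Casp4 at 8.05-fold (6.87 to 9.51). Among the 12 smallest ratios, Cfap52 was 6.86-fold lower (5.98 to 7.87), the sulfatide-forming enzyme gene Gal3st1 5.90-fold lower (5.18 to 6.72), Cmtm5 4.51-fold lower (3.86 to 5.27), Dlgap3 4.07-fold lower (3.51 to 4.71) and the Rap1 regulator gene Rap1gap 4.03-fold lower (3.72 to 4.36). Aif1l, Rnf144a, Fam89a, Plppr3, Serinc5 and Tspan11 were 3.62-fold, 3.49-fold, 3.30-fold, 3.27-fold, 3.09-fold and 2.96-fold lower.

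**Figure D1:**
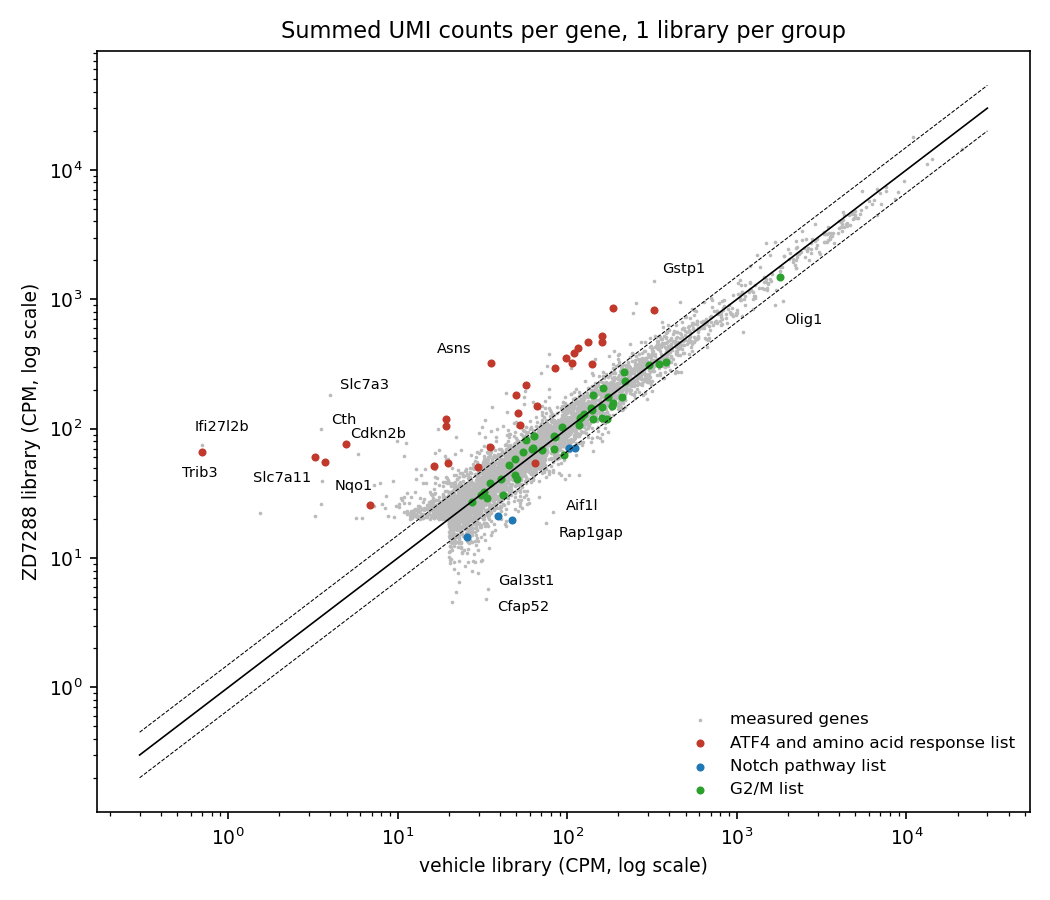
Level of each of the 4823 measured genes in the vehicle library (horizontal, CPM, log scale) and in the ZD7288 library (vertical, CPM, log scale), with equality as a solid line and 1.5-fold as dashed lines. Red points, the ATF4 and amino acid response list, lie above the line for 28 of 29 members, blue points, the Notch list, lie below it for all 5, and green points, the G2/M list, have a median log2 ratio of 0.00, which was -0.22 under a stricter cell filter, with at most 5% mitochondrial UMIs.

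Genes of the NRF2 oxidative stress response were also higher in the treated library, with 16 of 20 members higher, 0 lower and a median log2 ratio of 0.53 above all random lists. The quinone reductase gene Nqo1 stood at 39.2 CPM (37.8 to 40.6) against 3.59 CPM (2.71 to 4.66), and the haem oxygenase gene Hmox1 was 5.74-fold higher (5.08 to 6.50). Gstp1 was 4.30-fold higher (4.18 to 4.43), with the reservation that it has similar copies. Slc7a11 belongs to this list and to the ATF4 list. Lysosome and autophagy genes had 16 of 23 members higher and 0 lower, with a median of 0.51, among them the autophagy receptor gene Sqstm1 at 2.08-fold (1.93 to 2.24), Psap at 1.83-fold (1.75 to 1.91), Atp6ap1 at 1.80-fold (1.68 to 1.93) and Lamp2 at 1.71-fold (1.59 to 1.84). Of 25 ribosome biogenesis genes, 13 were higher and 0 lower, with a median of 0.32 at percentile 99.6 and Nop56 at 1.84-fold (1.76 to 1.93). Of 8 extracellular matrix genes, 4 were higher and 1 lower, led by Sparc at 3.89-fold (3.44 to 4.41) and Mdk at 2.94-fold (2.59 to 3.35). Markers of pericytes, fibroblasts and mesenchymal cells, summed, stood at 18.0 CPM in the treated and 1.73 CPM in the vehicle library.

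Genes of the p53 target list and a pair of cell cycle inhibitors were higher in the treated library as well. Whether p53 itself was involved was not tested. Of 15 measured p53 target genes 9 were higher and 0 lower, with a median log2 ratio of 0.53 (interval over members 0.02 to 1.63) at percentile 99.99. The stress gene Gadd45a was 3.99-fold higher (3.76 to 4.23) and the BH3-only gene Pmaip1 3.09-fold higher (2.81 to 3.40). Sesn2, 6.17-fold higher (5.50 to 6.95), is also a member of the ATF4 list, as is Ddit4. Among 5 CDK inhibitor genes, Cdkn2b was 10.9-fold higher (8.82 to 13.5) and Cdkn1a 3.47-fold higher (3.24 to 3.72). Cdkn2c and Cdkn3 of the same list were lower, at ratios of 0.722 (0.675 to 0.772) and 0.744 (0.716 to 0.773). Below the floor, and named after their values were seen, Cdkn1c was 2.60-fold lower (2.16 to 3.13) and Cdkn2a 1.52-fold higher (1.30 to 1.78). In the list of G1 cyclin, E2F and CDK genes 2 of 7 were higher and 0 lower. The G1 cyclin gene Ccnd2 was 2.49-fold higher (2.30 to 2.70) and Myc 1.46-fold higher (1.39 to 1.54). In the apoptosis list 2 of 7 genes were higher, Pmaip1 and the anti-apoptotic gene Bcl2l1 at 3.55-fold (3.25 to 3.89).

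Several lists lay on the other side. All 5 measured Notch pathway genes, of 19 matched, were lower in the treated library, with a median log2 ratio of -0.82 at percentile 0.03. Notch1 and Hes1 reached the floor in the vehicle library alone. Below the floor, and named after their values were seen, Jag1 was 2.02-fold higher (1.58 to 2.61), while Dll1 and Dll3 had ratios of 0.624 (0.546 to 0.713) and 0.440 (0.382 to 0.509). Notch1 was 2.40-fold lower (2.19 to 2.62), Notch2 1.87-fold (1.70 to 2.06) and the Notch effector gene Hes1 1.77-fold (1.57 to 1.98). All 3 measured Wnt pathway genes, of 27 matched, were lower, Tcf7l1 by the widest margin at 2.77-fold (2.45 to 3.14). The hedgehog receptor gene Ptch1, 1 of 2 measured genes of its list, was lower too, at 2.27-fold (2.03 to 2.54). Tcf7l1, at 26.0 CPM in vehicle and 9.38 CPM in treated cells, and Ptch1, at 28.9 and 12.7 CPM, also reached the floor in the vehicle library alone. Of 4 measured markers of oligodendrocyte precursors 3 were lower, with a median of -0.80 below all random lists. These, chosen after their values were seen like the other marker genes named here, were Cnp at 2.10-fold (2.00 to 2.21), Olig1 at 1.88-fold (1.86 to 1.91) and Olig2 at 1.61-fold (1.57 to 1.66). Markers of neural stem cells went both ways, with 3 of 11 higher and 5 lower, the stem cell factor gene Sox9 being 1.76-fold lower (1.67 to 1.85) and the glutamate transporter gene Slc1a3 1.58-fold higher (1.52 to 1.64). Of 3 measured neuron markers Gap43 was higher and Map2 lower, of 2 astrocyte markers Gja1 was higher, and the 1 measured marker of intermediate progenitors, Btg2, had a ratio of 0.992 (0.954 to 1.03). Of 12 mitochondrially encoded genes 6 were lower and 1, Mt-nd6, was higher, with a median of -0.27 at percentile 0.05. Under the stricter cell filter that median was 0.02.

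Endoplasmic reticulum chaperone genes did not move with the ATF4 list. Of 18 measured members 3 were higher and 7 lower, with a median log2 ratio of -0.19 at percentile 0.45. Sdf2l1 was 3.86-fold lower (3.41 to 4.37) and Creld2 1.68-fold lower (1.58 to 1.78), while Herpud1 was 2.25-fold higher (2.07 to 2.46). The remaining lists had medians within the range of their random lists or, for cytosolic ribosomal protein genes, a small shift to -0.15 with 2 of 36 members lower. Quiescence genes of neural stem cells had 6 of 17 higher and 3 lower, with a median of 0.15 at percentile 74.6 that was -0.14 in cells below 10 cell cycle UMIs. FGF and ERK feedback genes had 3 of 10 higher, Dusp6 at 1.53-fold (1.46 to 1.59), Spry1 and Etv4. Cholesterol genes had 3 of 20 higher and 2 lower, with a median of 0.15 that was -0.11 under the stricter cell filter. Higher and lower were, for fatty acid genes, 3 and 2 of 10, for hypoxia and glycolysis genes 4 and 6 of 19, for heat shock genes 2 and 1 of 13, and for DNA repair genes 1 and 2 of 13. Nuclear oxidative phosphorylation genes had 10 of 49 higher and 1 lower, with a median of 0.05 whose sign was reversed under both other scalings.

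**Figure D2:**
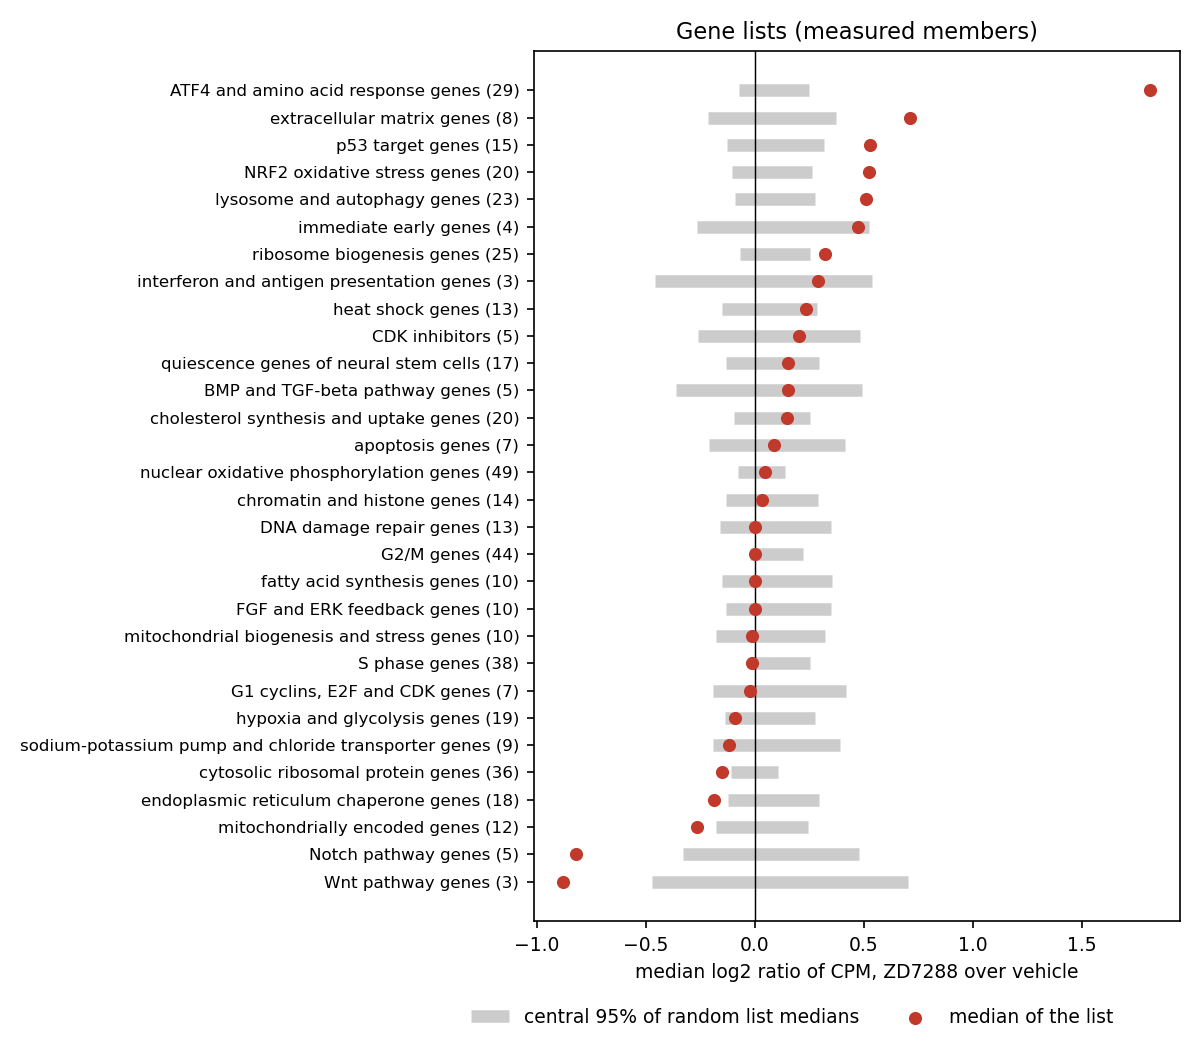
Median log2 ratio of CPM, ZD7288 over vehicle, for each gene list with at least 3 measured members (red points, number of members in parentheses), with the central 95% of medians of 10000 random lists matched on expression (grey bars). The ATF4 list lies at 1.82, the Notch list at -0.82, and the S phase and G2/M lists at -0.01 and 0.00, which were -0.27 and -0.22 under the stricter cell filter.

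Counted per cell, UMIs of the ATF4 list were more numerous in most treated cells. At 2000 UMIs per cell, treated cells held a mean of 14.3 list UMIs (SD over cells 5.73, 2956 cells) and vehicle cells 4.51 (SD 2.68, 724 cells). A Trib3 UMI was seen in 12.3% (11.1 to 13.5) of treated cells and in 0 of 724 vehicle cells, which at this depth allows a share of cells with a UMI of up to 0.414% by 3 counts, or 0.508% by the exact interval. Without thinning the shares were 54.0% and 1.23%. For Asns the thinned shares were 44.9% (43.1 to 46.7) and 7.46% (5.65 to 9.62), and the unthinned shares 92.7% and 41.8%. No cell type that should lack these genes was identified in the cultures, so the part of these UMIs, and of the cell cycle UMIs, that came from free RNA stayed open.

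**Figure D3:**
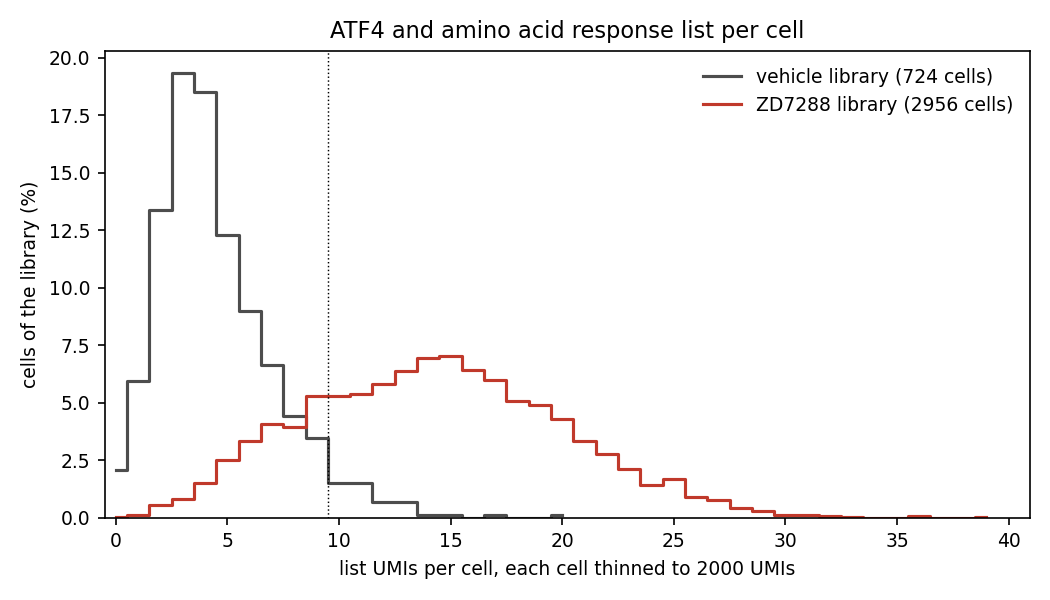
Share of cells of each library (vertical, %) by number of UMIs of the ATF4 and amino acid response list (horizontal), each cell thinned to 2000 UMIs, for the vehicle (grey) and ZD7288 (red) libraries. The treated cells have a mean of 14.3 UMIs and the vehicle cells 4.51, and the dotted line marks the vehicle 95th percentile of 9 UMIs.

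The cell cycle was compared because proliferation is the usual readout of such cultures. The lists had median log2 ratios of -0.01 for 38 S phase genes and 0.00 for 44 G2/M genes, which lay toward the low end of their random lists, at percentiles 3.67 and 6.74. Under the stricter cell filter the medians were -0.27 and -0.22. In cells below 10 cell cycle UMIs they were -0.31 and -0.03, and in cells from 10 UMIs 0.13 and 0.18. These ranges are split by UMIs of the same lists, so medians within them are not independent of the split. Within the G2/M list Mki67 was 1.51-fold lower (1.43 to 1.61) and Nuf2 1.44-fold higher (1.34 to 1.55) in the treated library. The threshold of 3 list UMIs set beforehand took in nearly all cells, 99.0% (98.0 to 99.6) of vehicle and 97.6% (97.0 to 98.1) of treated cells. At a threshold of 10 UMIs, added after the data were seen, 8.15% (6.26 to 10.4) of vehicle cells and 21.4% (19.9 to 22.9) of treated cells lay below it. The cells below 10 UMIs are a range of a score and not a cell type, and 11.9% of vehicle and 12.1% of treated cells had 8 to 12 UMIs. Mean list UMIs per cell were 20.2 (SD 8.50) and 18.6 (SD 9.72). Mki67 UMIs were seen in 15.2% (12.7 to 18.0) of vehicle and 10.5% (9.37 to 11.6) of treated cells, and without thinning in 62.8% and 52.8%. For Top2a the shares were 22.1% (19.1 to 25.3) and 16.0% (14.7 to 17.4), and without thinning 63.1% and 57.8%. Pcna, not among the genes planned for this measure, differed less, at 40.6% (37.0 to 44.3) and 36.5% (34.7 to 38.2), and without thinning 89.2% and 88.8%.

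**Figure D4:**
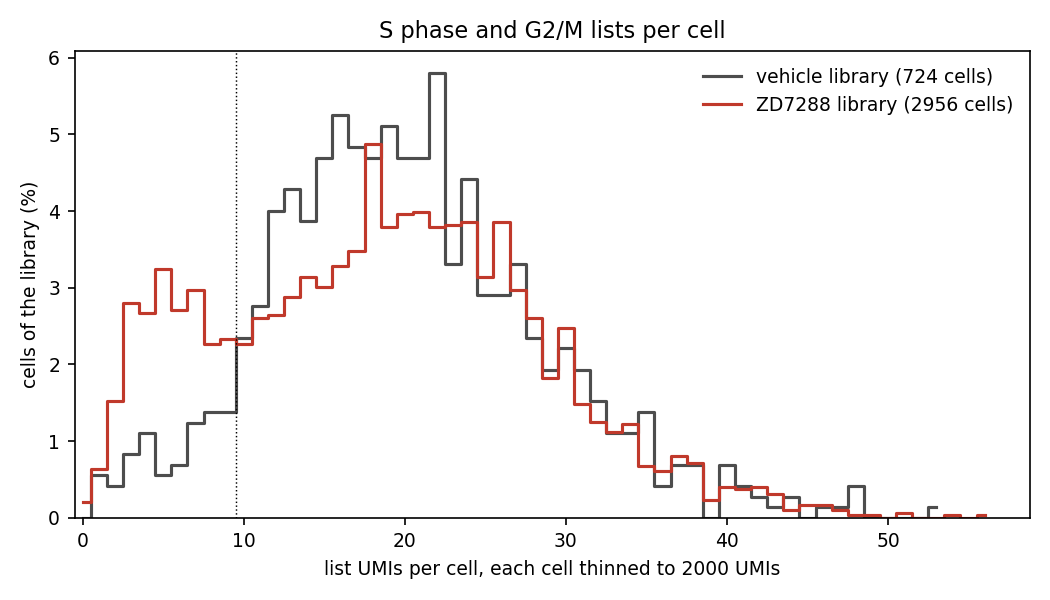
Share of cells of each library (vertical, %) by number of UMIs of the S phase and G2/M lists (horizontal), each cell thinned to 2000 UMIs, for the vehicle (grey) and ZD7288 (red) libraries. Below 10 UMIs, at the dotted line, lie 8.15% of vehicle and 21.4% of treated cells.

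Gene ratios were also taken within ranges of the cell cycle score, added after the data were seen, with 59 vehicle and 632 treated cells below 10 UMIs and 665 and 2324 cells from 10 UMIs. The ATF4 list had a median log2 ratio of 1.85 in the lower range and 1.80 in the upper, and in each library the median cell of both ranges held the same number of list UMIs, 4 in vehicle and 14 in treated cells. The NRF2 list had medians of 0.66 and 0.51. Cdkn1a stood at 147 CPM (122 to 175) in vehicle and 256 CPM (248 to 265) in treated cells of the lower range, and at 51.5 CPM (47.9 to 55.3) and 181 CPM (178 to 185) in the upper. Cdkn2b was 3.65-fold higher (2.38 to 5.92) in treated cells of the lower range and 11.8-fold higher (9.34 to 15.2) in the upper. The Notch list had medians of -1.64 over 7 measured members and -0.69 over 5.

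Clustering without the members of the S phase and G2/M lists separated the libraries almost completely. Cell cycle genes outside these lists, such as Prc1, were not left out. The clusters are given by number because none could be named as a cell type. Cluster 2 held 95.9% (94.2 to 97.2) of vehicle cells and 1.40% (1.02 to 1.88) of treated cells, 702 and 44 cells. The others were 1183, 628, 563, 452 and 265 treated cells in clusters 1, 3, 4, 5 and 6, with 18, 1, 4, 2 and 5 vehicle cells. S phase genes led cluster 1, with Dscc1 and Pcna, and mitotic genes led cluster 3, with Plk1, Aurka and Cdc20. In treated cells of cluster 1 the S phase and G2/M lists had medians of 0.48 and -0.20 against the whole vehicle library. These medians were -0.48 and 1.03 in cluster 3, -0.94 and -2.24 in cluster 4, and -0.41 and -0.74 in cluster 5. The treated clusters thus differed in their levels of cell cycle genes. Cluster 4 was led by Ifi27l2b, Col3a1 and Col1a1, the collagens coming from few cells, and had a mean of 6.43 cell cycle UMIs. Cluster 6 had a median of 1610 UMIs per cell and 0.679% mitochondrial UMIs and held 8.45% (7.50 to 9.48) of treated and 0.683% (0.222 to 1.59) of vehicle cells. Against the whole vehicle library, the ATF4 list had medians of 1.69, 1.94, 1.79, 1.78 and 1.84 in the treated cells of clusters 1, 3, 4, 5 and 6. With 1 library per group, a cluster mostly of 1 library can be that library and not a type of cell.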

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

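The threshold of 10 cell cycle UMIs, the tests on low-UMI or stripped cells below it, the counts of list UMIs among cells that clustered with the other library and the test on endoplasmic reticulum chaperones were chosen after the results they concern were seen, and the other tests were set before, except that the 50% bound was applied to the share of ATF4-high cells after its value was seen. The ATF4 and amino acid response list was also higher in the treated library among the barcodes that the cell filter left out, outside the main measurement. In 110 vehicle and 714 treated barcodes the list stood at 3259 and 8395 CPM, a ratio of 2.58 (2.42 to 2.74).

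The 28 ATF4 response genes that were higher in the treated library were set against technical explanations. Of treated cells, 77.8% (76.3 to 79.3) lay above the vehicle 95th percentile of list UMIs at 2000 UMIs per cell, above the 50% that a signal carried by a minority of damaged or low-UMI cells could give, although the 80% set beforehand for excluding it was not reached. A list median of 1.72 after thinning every cell to 2000 UMIs decided nothing on a difference in depth. CPM ratios are already scaled to the library totals, so thinning was bound to leave the median near its value. General endoplasmic reticulum stress would raise the chaperones above the upper end of their random lists, 0.29. Their median was -0.19 (-0.39 to 0.08), so the chaperone list as a whole was not raised in the treated library. Members lay on both sides, 3 higher and 7 lower of 18, so stress that raises only part of them stays open. The state of the treated culture and the effect of the compound cannot be told apart with 1 treated culture, so a response to ZD7288 remains a hypothesis.

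The group of treated cells with few cell cycle UMIs was set against technical explanations in the same way. Removal of the low-UMI cluster could decide nothing on low-UMI or stripped cells, because thinning had already left out most of that cluster. In a test that took its place, 49.8% (45.9 to 53.8) of the 632 treated cells below 10 UMIs were among the lowest 25% of treated cells by UMIs before thinning or by mitochondrial share, on both sides of a bound of 50%, which decided nothing because 42.5% of all treated cells were among these. In a further test, chosen after that value was seen, 18.6% (16.8 to 20.6) of the 1701 treated cells outside both ranges lay below 10 UMIs. Within the same bounds were 295 vehicle cells, of which 3.05% (1.40 to 5.71) lay below 10 UMIs. That share was lowered by the bounds, which were set on treated cells. Vehicle cells below 10 UMIs had a median of 12649 UMIs before thinning, against a bound of 18873. The treated share also lay above the 8.15% (6.26 to 10.4) of all vehicle cells, which argues against low-UMI or stripped cells as the whole cause. At 4000 UMIs per cell and a threshold of 20, the shares were 21.6% (20.1 to 23.2) of treated and 8.38% (6.46 to 10.7) of vehicle cells. This decided nothing on a difference in depth. The shares below 10 UMIs were already taken at an equal number of UMIs per cell. With depth and threshold raised together, the shares were bound to stay near their values. Fewer cycling cells under the compound may account for the group, but with 1 treated culture the compound and the state of that culture cannot be told apart.

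Cells that clustered with the other library, 44 treated cells and 25 vehicle cells outside the low-UMI cluster, were the last pattern weighed. Of these 69 cells 0% (0 to 5.21) carried a barcode sequence also present in the other library, where swapped indices would give at least 50%, with an upper limit just over the 5% set beforehand. Of the 44 treated cells 0% (0 to 8.04) were among the cells marked as doublets. Their ATF4 list median against the vehicle library was 0.63, above the random lists (-0.07 to 0.26) and below the value of 1 set beforehand for a response, so cells that did not respond and cells that responded in part cannot be told apart. Above 9 list UMIs lay 16 of 41 thinned treated cells and 8 of 25 vehicle cells of this kind. Of all vehicle cells 4.97% lay above it, which follows from a threshold set at an upper percentile of these cells. Genes of the ATF4 list were not left out of the clustering, so a cell's level of them could help decide its cluster. Treated cells in the vehicle cluster could thus be picked for low levels and vehicle cells in treated clusters for high ones. The median of 0.63 and these counts therefore decide nothing on whether the cells responded.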

How the results depend on the processing

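The cell cycle thresholds of 10 and 15 UMIs, the range below 10 UMIs and the removal of the low-UMI cluster were chosen after the data were seen. Of 357 list medians under another setting, 339 stayed within the interval of the median, or within the wider range of the members for lists with fewer than 6 of them (82 of the 357), 16 moved and 2 were reversed. A reversal was counted only where that interval or range excluded 0, and the sign differed in 49 comparisons over 17 lists, most of these comparisons being of lists with a median near 0 in whole libraries. In cells below 10 cell cycle UMIs the medians of quiescence, interferon and BMP genes were -0.14, -0.10 and -0.40, and under the stricter cell filter those of cholesterol and mitochondrially encoded genes were -0.11 and 0.02, each of the other sign. In lists of few members a large shift could pass, the median of immediate early genes being 0.47 and, at a floor of 50 CPM, -0.01, with each cell weighted equally 1.04, and in cells below 10 cell cycle UMIs 1.55. The genes of largest and smallest ratio stayed within their counting intervals in 165 and moved in 51. The ATF4 list ranged from 1.47 to 1.85 and the NRF2 list from 0.44 to 0.66. The median of nuclear oxidative phosphorylation genes was reversed to -0.015 under median-ratio scaling and to -0.0054 under totals without ribosomal, mitochondrial and top genes, which shift all log2 ratios by 0.06 and 0.05. The stricter cell filter, which keeps 163 vehicle and 1675 treated cells, gave medians of -0.27 for S phase, -0.22 for G2/M and 1.47 for ATF4 genes and a vehicle share of 100% with at least 3 cell cycle UMIs, and the cause was not tested. In cells below 10 cell cycle UMIs, 864 genes were higher and 463 lower, with medians of -0.31 for S phase and -1.64 for Notch genes, from 59 vehicle cells, and the cause was not tested. A floor of 10 CPM gave 418 lower genes, and a floor of 50 CPM gave 272 higher and 83 lower. A size of 0.32 on the log2 scale gave 1298 and 651 genes and the 2-fold rule 139 and 61. The shares with at least 3 cell cycle UMIs were, in vehicle and treated cells, 96.3% and 89.3% at 1000 UMIs, 99.9% and 99.97% at 4000 UMIs, 88.5% and 79.5% with the S phase list alone, and 95.2% and 90.0% with the G2/M list alone. A threshold of 2 gave 99.2% of treated cells, and thresholds of 5, 10 and 15 gave 97.1% and 92.2%, 91.9% and 78.6%, and 74.6% and 65.1%. Resolution 1.0 left 71.9% of vehicle and 0.574% of treated cells in the main vehicle cluster, and 4000 variable genes left 0.797% of treated cells there, and the cause was not tested. The planned comparison within cells below 3 UMIs was not run, with 7 vehicle and 70 treated cells against the 50 required. No paired analysis was possible because each group has 1 library. Depth limits the vehicle side, where Trib3 and Ifi27l2b rest on 11 UMIs each.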

Other observations

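The test on tRNA synthetases was set before its result was seen, and the counts of collagen and other mesenchymal genes per cluster and the comparison within treated cells were chosen after. Among treated cells outside the low-UMI cluster, the 617 cells below 10 cell cycle UMIs were compared with the 2244 others. Fam43a was 3.77-fold higher (3.41 to 4.17) in the first group, Vat1 3.11-fold (2.67 to 3.61) and G0s2 2.99-fold (2.56 to 3.48). Cdkn2b was 1.67-fold (1.57 to 1.78) and Cdkn1a 1.42-fold (1.36 to 1.47) higher. Genes of the ATF4 list differed among themselves, with Trib3 at 1.44-fold (1.34 to 1.53), Slc7a11 at 1.17-fold (1.09 to 1.26) and Asns at 1.03-fold (0.994 to 1.06). Cdkn1a and Cdkn2b were also higher in vehicle cells below 10 cell cycle UMIs than in vehicle cells from 10 UMIs. Cdkn1a stood there at 147 against 51.5 CPM, and Cdkn2b at 25.7 against 4.74 CPM, the latter over 21 and 70 UMIs. Higher levels of these 2 genes below 10 UMIs were thus not limited to treated cells.

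Genes of ion pumps differed in both directions. Of 9 measured genes of the sodium-potassium pump and chloride transporter list, 4 were higher and 3 lower in the treated library, Atp1b1 at 3.25-fold higher (2.96 to 3.56) and Fxyd6 at 2.05-fold lower (1.88 to 2.24). Among 4 immediate early genes Ier5 was 3.91-fold higher (3.45 to 4.45) and Jun 1.94-fold higher (1.75 to 2.16), while Egr1 was 1.40-fold lower (1.33 to 1.47). Of 10 mitochondrial biogenesis and stress genes 3 were higher, among them the protease gene Lonp1 at 1.80-fold (1.68 to 1.93), and 1 was lower. Of 5 BMP and TGF-beta pathway genes Id1 was 2.23-fold higher (2.11 to 2.37) and 2 were lower, Bmp7 and Id2. Of 14 chromatin genes 1 was higher and 3 lower, Chd7 at 1.56-fold (1.47 to 1.67). Of 3 interferon and antigen presentation genes Psmb9 was higher, at 1.92-fold (1.68 to 2.19).

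Collagen transcripts in the treated library sat in few cells. In cluster 4, 185 Col1a1 UMIs came from 7 of 563 treated cells, 1.24% (0.501 to 2.54), and 181 Col3a1 UMIs came from 9 cells, 1.60% (0.734 to 3.01). In cluster 2, 2 of 702 vehicle cells held a Col1a1 UMI. The mesenchymal marker sum did not rest on these cells alone. Tagln, chosen after its values were seen, gave 607 of the 1323 UMIs of that sum in the treated library and was seen in 95 of 1183, 53 of 628, 68 of 563 and 30 of 452 treated cells of clusters 1, 3, 4 and 5. Summed markers of oligodendrocytes, microglia and macrophages, endothelial cells, erythroid cells and choroid plexus stood at 2.56, 1.47, 0.897, 0.0641 and 0.769 CPM in the vehicle library and at 1.19, 1.44, 2.00, 0.0136 and 0.896 CPM in the treated library.

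A hypothesis was that cytosolic tRNA synthetase genes outside the fixed ATF4 list are higher as a whole and mitochondrial ones are not. The median log2 ratio of 12 cytosolic genes was 0.79, above the random lists (-0.12 to 0.33), with 11 higher and Qars at 0.865-fold (0.818 to 0.916). Eprs stood out at 4.86-fold (4.59 to 5.15) and Lars at 3.03-fold (2.81 to 3.28), chosen after their values were seen. Of 17 mitochondrial genes 3 were measured, with a median of 0.58 and 2 higher, which is too few to decide the other part of the hypothesis.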
